A study of Mus musculus with 9 samples.

How the data were processed

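The samples were 9 RNA sequencing libraries of mouse cardiac endothelium. Per the labels, endothelial cells were taken from fresh heart tissue with Miltenyi microbeads, and the bound cells were collected on an autoMACS instrument. PolyA RNA was fragmented and copied with random hexamers, and libraries were read with 100-cycle single reads on an Illumina HiSeq instrument. The strandedness of the libraries and the annotation release were not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, FastQC, TopHat2 2.0.13, Bowtie2, featureCounts of Subread, edgeR and the mouse genome build mm9, with no roles, order or settings.

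The authors deposited a single table of 18094 genes. Per the file headers and the values, 9 of its columns hold raw counts, and the smallest total of a gene over the 9 libraries was 10 counts. The deposited CPM values equal each count divided by the total of its column and scaled to CPM, with no other factor. The deposited log2 fold changes and the deposited p-values (p_value) with their false discovery rates come from the authors' own comparisons, whose model and filter were not given in the sources used here. A further deposited column holds gene lengths, which were not used. A spreadsheet had turned 21 symbols into calendar dates, and these were named again through their Ensembl identifiers in the GENCODE M21 annotation. A further 854 genes without a symbol kept their identifier, and 6 genes shared a symbol with another. The GENCODE annotation belongs to a later build than mm9, so it served for names, gene types and the order of neighbouring genes, and no coordinates are printed.

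Libraries fell into 3 groups of 3 by the strain and age in their labels. Depth ran from 28806840 to 32913813 counted reads per library. A floor of 3 counts, the upper 95% limit that a count of 0 allows, corresponded to 0.0911 to 0.104 CPM. Reads carry no molecular identifiers, so such floors cover counting error only.

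Genes were kept by filterByExpr, which left 15277, and libraries were scaled by trimmed mean of M values (TMM). All 9 libraries entered a single quasi-likelihood fit on group in edgeR 4.0.16, whose default in this version is the legacy fit. Each contrast used the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. CPM values printed with an SD carry the TMM scaling, except for Uty. The values of Xist, Ddx3y and Uty were scaled by library totals alone. Gene lists were written before the data were examined, from textbook knowledge of endothelial function, of other heart cell types and of general cell processes. The 45 lists with at least 5 measured genes were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. Work was done in R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9 for figures.

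Genes to be named were fixed by a rule for each contrast. The rule took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in the higher group, no overlap between groups and a symbol that was not of a predicted or clone type. It added the 2 called members with the smallest adjusted p in each direction from each list described, 15 genes of endothelial and blood pressure interest whatever their result, and the most abundant marker of each other cell type.

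Overlaps between contrasts were compared with the overlap of independent lists and with 20 simulated data sets in which unchanged groups shared the control libraries. A further 20 simulated data sets, in which 4-week BPH/2J equalled BPN/3J, gave the ratio of the 4-week to the 22-week difference expected without a change. Equal replicate numbers were checked for a shared batch by correlating the residuals of libraries with equal numbers.

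The alternatives were median-of-ratios and upper-quartile scaling, TMM without genes of the other cell types, no low-count filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the edgeR exact test, robust and legacy quasi-likelihood fits, fits on only the groups compared, the replicate number as a block, the mean log2 CPM of the cardiomyocyte list as a covariate, an adjusted p threshold of 0.01, and leaving out each library in turn. The fit with the legacy setting off and the fit without annotated pseudogenes were chosen after seeing the data.

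The pipeline was tested on simulated data with 200 changed genes per comparison, drawn only from genes above a minimum mean count. Recovery at low counts was thus not measured, and far fewer genes changed than were called in the data. The shares that follow hold for that setting only. The quasi-likelihood test recovered 67%, 67% and 66% of genes changed 1.5-fold and 90%, 88% and 89% of genes changed 2-fold, in the order of the comparisons below. Of its calls in the simulation, 3.68%, 3.12% and 6.63% were unchanged genes, and 0 of 45 unchanged lists were called in any comparison. Simulated genes were drawn independently of one another, so the list test was not checked against correlation between genes. The share of unchanged genes among calls was 11.3% to 16.3% for DESeq2 and 16.1% to 20.6% for the exact test.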

Results

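RNA sequencing read counts were collected from endothelial cells sorted from the hearts of a pair of inbred mouse lines. BPH/2J is a line bred for high blood pressure, and BPN/3J is the normotensive line kept beside it. Cells came from BPH/2J at 4 weeks and at 22 weeks of age and from BPN/3J at 22 weeks, with 3 libraries per group. The BPN/3J libraries held 29971150, 29769820 and 28806840 counts. The 4-week BPH/2J libraries held 30202225, 29652150 and 32913813 counts, and the 22-week BPH/2J libraries held 30137015, 30391861 and 30276325. Between 17769 and 17852 genes had a count in a library, and the 10 most abundant genes took 5.12% to 6.27% of counts. Endothelial cadherin, Cdh5, reached 2405 ± 41.9 CPM in BPN/3J, 3181 ± 94.1 in 4-week BPH/2J and 3049 ± 202 in 22-week BPH/2J (mean ± SD, n = 3, as in all values given with CPM). Xist, the transcript of the inactive X chromosome, stayed at or below 0.174 CPM in every library, and the Y-linked Ddx3y averaged 112 to 153 CPM in the groups.

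The first principal component of log2 CPM held 59.7% of the variance and placed the BPN/3J libraries between -64.7 and -61.4 and the BPH/2J libraries between 10.9 and 50.3. The first component also set the ages of BPH/2J apart, with 22-week libraries at 10.9 to 19.6 and 4-week libraries at 46.6 to 50.3. The second component held 23.3% and separated these ages too. On it the 22-week BPH/2J libraries lay at -44.5 to -30.2 and the 4-week libraries at 16.2 to 33.9. The BPN/3J libraries lay at 6.82 to 16.1, next to the 4-week BPH/2J libraries. The third held 5.22%, with replicate 1 of 4-week BPH/2J at -35.1 and replicates 2 and 3 on the positive side. That library also carried 2.63% mitochondrial counts, against 1.19% and 1.33% in the other libraries of its group. Correlations of log2 CPM were at least 0.988 within groups and at most 0.981 between groups, across genes, which are not independent replicates. Nothing in the labels says that the replicates are separate animals, so the p-values measure the spread between these libraries, which may be technical. A gene described as higher, lower, risen or fallen passed the edgeR test, and its 3 libraries in each group did not overlap, unless an overlap is stated.

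**Figure D1:**
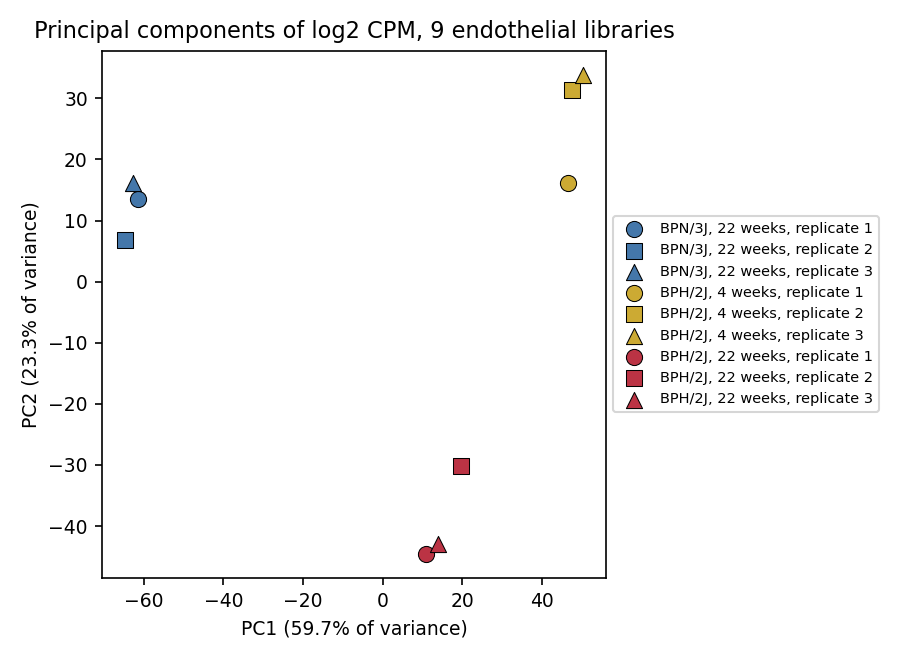
Principal components of log2 CPM for the 9 libraries, with the first component (59.7% of variance) on the x axis, the second (23.3%) on the y axis and colours for the 3 groups. BPN/3J libraries lie below -61 on the first component, and the BPH/2J libraries of both ages lie above 10.

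The comparison of the lines at 22 weeks asked which endothelial transcripts differ between the hypertensive and the normotensive line at equal age. Each blood pressure state is represented by a single line, so blood pressure and strain background cannot be separated. Targets of the glucocorticoid receptor were lower in BPH/2J: 17 of 21 measured members were lower and 0 were higher, and the counts adjusted over the list alone were also 17 and 0 (camera adjusted p = 2.84e-13; adjusted p = 0.0678 with an estimated correlation). Cdkn1a, a cyclin-dependent kinase inhibitor, was at 68.0 ± 8.03 CPM in BPH/2J and 365 ± 9.67 CPM in BPN/3J, a log2 difference of -2.42 ± 0.10 (SE, adjusted p = 7.77e-08). Klf15, a transcription factor of metabolic genes, was 6.15-fold lower in BPH/2J, at 5.47 ± 0.326 against 33.6 ± 2.97 CPM (adjusted p = 2.91e-07). Immediate early genes, which respond within minutes to growth factors, stress and tissue dissociation, were also lower, with 24 of 30 lower and 0 higher, or 27 and 0 adjusted over the list alone (adjusted p = 7.98e-11; adjusted p = 0.698 with an estimated correlation). Among them Csrnp1 stood at 66.3 ± 7.11 CPM in BPH/2J against 277 ± 9.34 in BPN/3J, and Dusp1, a phosphatase of MAP kinases, at 637 ± 44.8 against 1258 ± 96.6.

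Across all 15277 tested genes, 3024 were higher and 2786 lower in BPH/2J, 38.0% of genes in all. Of these, 517 were higher and 835 lower by 2-fold or more. The CPM ranges of the groups did not overlap for 55.7% of tested genes, against 10% by chance. The deposited table of the authors lists 3153 higher and 2848 lower genes for the same contrast, of which 5267 were called in the same direction here and 0 in the opposite one.

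Regulators tied to blood flow and vascular tone differed in both directions. The flow-responsive transcription factors Klf2 and Klf4 were lower in BPH/2J by log2 differences of -1.10 ± 0.11 and -1.15 ± 0.07 (adjusted p = 3.37e-05 and 2.08e-06). Of the 25 shear-stress genes measured, 4 were higher and 6 lower, as also when adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.56). Ahr, the aryl hydrocarbon receptor, was higher at 95.6 ± 1.75 against 47.7 ± 4.69 CPM. The apelin receptor Aplnr was 6.15-fold higher in BPH/2J, at 414 ± 73.1 against 67.3 ± 9.09 CPM (adjusted p = 4.27e-07). The endothelin B receptor Ednrb was 1.99-fold lower, at 135 ± 6.97 against 269 ± 20.3 CPM, and the bradykinin receptor Bdkrb2 was 2.62-fold lower. Calcrl, the receptor that binds adrenomedullin and its relatives, was 1.48-fold higher. In the list of vasoactive peptide genes, 4 of 28 were higher and 10 lower (4 and 12 adjusted over the list alone), and the list was not called (adjusted p = 0.459).

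The mechanosensitive calcium channel Trpv4 was 2.67-fold higher in BPH/2J, at 66.4 ± 2.94 against 24.8 ± 1.47 CPM, and the connexin gene Gja4 was 2.76-fold higher. Pkd2 and Itpr3, which encode calcium channels of internal membranes among other sites, were lower by log2 differences of -0.65 ± 0.05 and -0.50 ± 0.06. The ion channel and connexin list had 11 of 49 members higher and 8 lower, equal to the counts adjusted over the list alone, with no shift as a list (adjusted p = 0.607). Endothelial nitric oxide synthase, Nos3, gave 280 ± 10.9 and 282 ± 2.76 CPM, and no difference was detected (log2 difference -0.01 ± 0.08, adjusted p = 0.954). Around it, Qdpr, which regenerates the cofactor of nitric oxide synthase, was higher by 0.76 ± 0.07 on the log2 scale, and Gch1, which makes that cofactor, was lower at 40.9 ± 0.600 against 62.7 ± 4.13 CPM. Of the 24 nitric oxide and cGMP genes, 6 were higher and 2 lower, with equal counts adjusted over the list alone (adjusted p = 0.215). The angiotensin-converting enzyme Ace and the endothelin precursor Edn1 had adjusted p = 0.846 and 0.706. In the renin-angiotensin list 2 of 15 were higher and 4 lower, also when adjusted over the list alone (adjusted p = 0.302), among them Agtrap, which binds the angiotensin receptor, at 42.7 ± 0.526 against 66.2 ± 3.62 CPM.

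**Figure D2:**
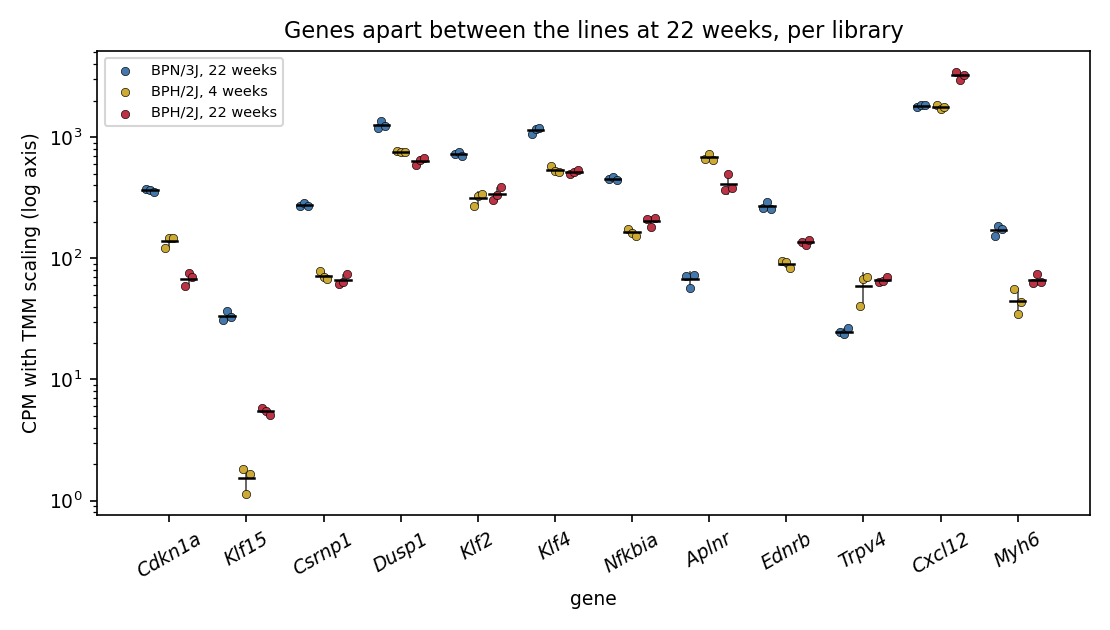
CPM with TMM scaling (log axis) of 12 genes in each of the 9 libraries, coloured by group, with the mean as a bar and the SD as a vertical line (n = 3). Cdkn1a, Klf15, Csrnp1, Klf2 and Klf4 lie lower in both BPH/2J groups than in BPN/3J, and Aplnr and Trpv4 lie higher.

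Genes of endothelial junctions and the barrier were higher in BPH/2J, with 13 of 31 higher and 3 lower, or 17 and 3 adjusted over the list alone (adjusted p = 0.0263; adjusted p = 0.689 with an estimated correlation). Marveld2, the tight junction protein tricellulin, was at 10.3 ± 1.72 against 0.841 ± 0.163 CPM, and Cldn5, the main claudin of endothelium, was lower at 174 ± 14.4 against 249 ± 30.1 CPM. Without BPN/3J replicate 1 the list had an adjusted p of 0.0664. Among general endothelial markers 12 of 25 were higher and 4 lower (13 and 4 adjusted over the list alone), with Myct1 1.91-fold and Clec14a 1.81-fold higher and Sox17 1.62-fold lower, and the list was not called (adjusted p = 0.0739). The chemokine Cxcl12 was higher, at 3229 ± 231 CPM in BPH/2J and 1823 ± 37.2 CPM in BPN/3J. The NF-kappaB inhibitor Nfkbia was 2.25-fold lower. Of the 36 adhesion and cytokine genes 6 were higher and 12 lower, or 7 and 12 adjusted over the list alone, and neither Vcam1 (adjusted p = 0.169) nor Icam1 (adjusted p = 0.119) was called. That list had a median log2 difference of 0.01 and a mean of -0.24, and its test was not past the threshold (adjusted p = 0.353).

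Antigen presentation genes were lower in BPH/2J, with 19 of 25 lower and 0 higher, or 20 and 0 adjusted over the list alone (adjusted p = 2.17e-06; adjusted p = 0.698 with an estimated correlation). The class I genes H2-Q6 and H2-Q10 were lower by log2 differences of -1.69 ± 0.18 and -1.61 ± 0.14. Whether sequence variants moved reads between related copies of these genes was not tested. Interferon-stimulated genes included 17 of 41 lower and 4 higher, as also adjusted over the list alone (adjusted p = 0.0114; adjusted p = 0.907 with an estimated correlation). Slfn8 was 18.8-fold lower and Xaf1 2.59-fold lower in BPH/2J. The interferon list had an adjusted p of 0.0725 without 22-week BPH/2J replicate 3. Beside these lists, macrophage and monocyte markers had 12 of 23 members lower and 2 higher in BPH/2J (13 and 2 adjusted over the list alone), with Cd14 at 11.5 ± 1.03 against 32.7 ± 8.98 CPM and Cd68 at 13.5 ± 1.89 against 23.2 ± 1.85 CPM (adjusted p = 0.0263; adjusted p = 0.812 with an estimated correlation). BPN/3J replicate 1 stood above replicates 2 and 3 in the mean log2 deviation of these 3 lists, with 1.14 against 0.61 and 0.46 for antigen presentation, 0.61 against 0.08 and 0.12 for interferon and 0.51 against -0.22 and -0.01 for macrophage genes. Without it the macrophage list had an adjusted p of 0.123, and the antigen presentation and interferon lists stayed past the threshold.

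Cardiomyocyte transcripts were lower in BPH/2J as well, with 15 of 24 markers lower and 0 higher, or 16 and 0 adjusted over the list alone (adjusted p = 0.000127; adjusted p = 0.698 with an estimated correlation). The cardiac myosin heavy chain Myh6 was at 66.8 ± 6.44 CPM in BPH/2J and 171 ± 15.2 CPM in BPN/3J, and skeletal actin Acta1, which cardiomyocytes express in development and under stress, was at 5.12 ± 2.09 against 65.9 ± 37.0 CPM. Heat shock and unfolded protein genes were lower as a list too in this comparison, with 15 of 30 lower and 1 higher, also when adjusted over the list alone (adjusted p = 0.00205; adjusted p = 0.698 with an estimated correlation), among them the co-chaperone Dnaja1 at 332 ± 7.54 against 928 ± 217 CPM. Over the heat shock list, BPN/3J replicate 1 had a mean log2 deviation of 0.03 against 0.28 and 0.31 in its group. The 22-week BPH/2J libraries lay at -0.38 to -0.29. Mitochondrial transcripts took 2.02% to 2.78% of counts in BPN/3J and 1.45% to 1.91% in 22-week BPH/2J. The pericyte marker Rgs5 was higher in BPH/2J, at 776 ± 69.2 against 470 ± 50.4 CPM, and of the 18 pericyte and smooth muscle markers 1 was higher and 2 lower (1 and 1 adjusted over the list alone; adjusted p = 0.686).

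Clock genes differed in opposite directions. Nr1d1 and Dbp, a repressor and an output factor of the circadian clock, were 2.75-fold and 3.28-fold higher in BPH/2J, while the clock repressor Per2 was 2.85-fold lower, at 166 ± 28.9 against 474 ± 65.4 CPM. Of the 21 clock genes 2 were higher and 9 lower, as also adjusted over the list alone (adjusted p = 0.539). The hour of tissue collection was not given in the sources used here. Ribosomal protein genes as a list were higher in BPH/2J by a median log2 difference of 0.19, with 7 of 64 higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.00572; adjusted p = 0.907 with an estimated correlation). Rpl26 was 4.06-fold and Rplp0 2.20-fold higher, and without BPN/3J replicate 3 the list had an adjusted p of 0.0993.

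Among the largest differences between the lines, Lppr1 (ENSMUSG00000063446, chromosome 4), which encodes a membrane protein known from neurons, was at 89.8 ± 14.7 CPM in BPH/2J and 0.126 ± 0.0184 in BPN/3J. Gdpd3 (ENSMUSG00000030703, chromosome 7), an enzyme of lysophospholipid metabolism, was at 498 ± 34.8 against 8.88 ± 1.48 CPM. In the other direction, Rab6b, a small GTPase of the Golgi, was at 2.01 ± 1.02 CPM in BPH/2J and 63.2 ± 14.6 in BPN/3J, and the lectin receptor Clec12b at 0.140 ± 0.0375 against 9.71 ± 0.875 CPM. Serpina3h, of the serine protease inhibitor family, was at 0.0860 ± 0.0371 against 33.2 ± 15.5 CPM. Related copies of other genes were prominent: Tpm3-rs7 was at 151 ± 0.703 against 0.837 ± 0.243 CPM, and the pseudogene Rps3a3 at 0.344 ± 0.0802 against 196 ± 25.9 CPM. Of the 211 transcripts at least 3 apart on the log2 scale, 66 (31.3%) are annotated pseudogenes, against 1.93% of the other 15066 tested genes, so levels of single copies are uncertain.

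As limits on this comparison, 3661 genes were called with the mean cardiomyocyte level as a covariate, of which 2719 were also among the 5810. Of the 133 called genes that the naming rule took here, 25 lost their call under the covariate and 3 turned in direction. Among the lost calls were Pecam1 (adjusted p = 0.123), Cdh5 (adjusted p = 0.141) and Cldn5 (adjusted p = 0.305), and the junction list (adjusted p = 0.181) was no longer past the threshold. With the replicate number as a block, 5261 genes were called.

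**Figure D3:**
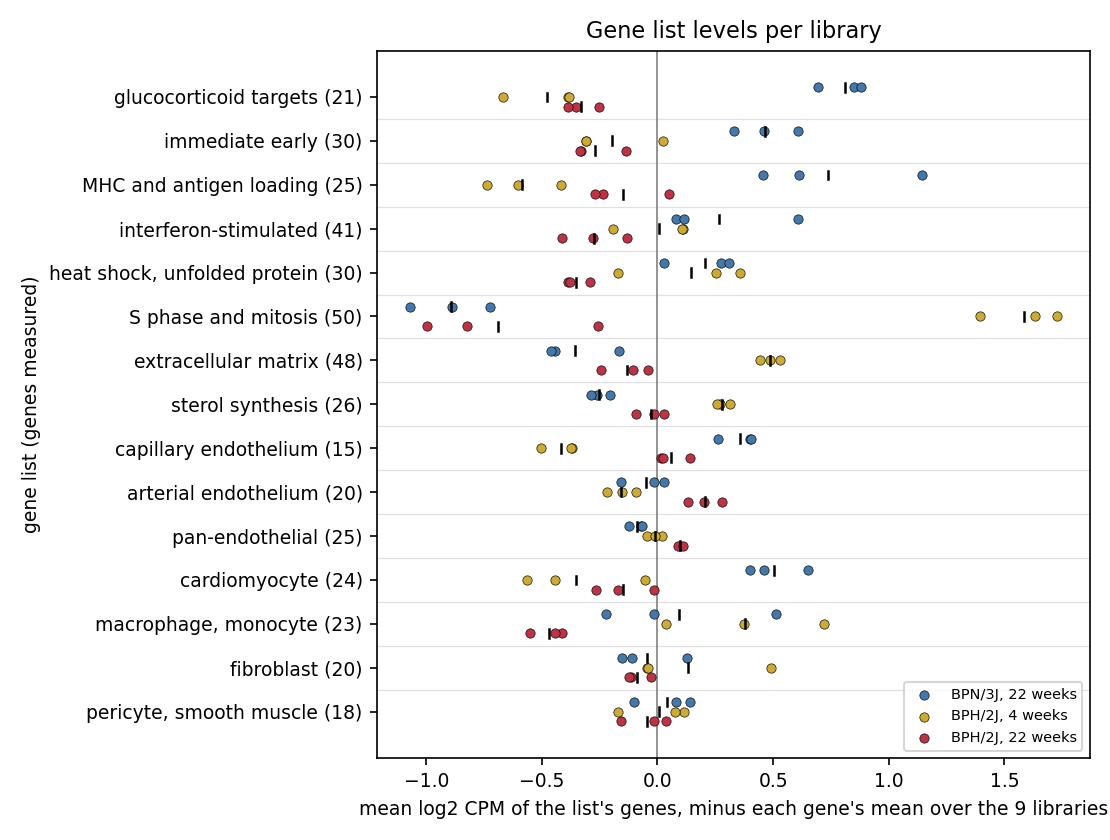
Mean log2 CPM of the genes of each list shown, minus each gene's mean over the 9 libraries. Each point is a library, coloured by group, and the bar is the group mean. Cell cycle genes lie between 1.40 and 1.73 in 4-week BPH/2J and between -1.07 and -0.26 in the other groups. Glucocorticoid targets lie between 0.70 and 0.88 in BPN/3J and between -0.67 and -0.25 in BPH/2J.

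The comparison of ages within BPH/2J asked how the endothelium of the hypertensive line differs between 4 and 22 weeks. Cell cycle genes fell with age without exception in the list, with 50 of 50 lower at 22 weeks over all genes and also adjusted over the list alone (adjusted p = 6.08e-73; adjusted p = 0.288 with an estimated correlation). The mitotic kinase Cdk1 fell from 37.9 ± 3.90 to 4.37 ± 1.45 CPM, a log2 change of -3.12 ± 0.20 (adjusted p = 8.17e-06), and the mitotic kinesin Kif23 fell from 55.7 ± 4.96 to 8.31 ± 2.21 CPM. Replicate 2 of 22-week BPH/2J stood apart in its group, with a mean log2 deviation over the list of -0.256 against -0.997 and -0.822, and the list was also called without it. Extracellular matrix genes fell as a list, with 29 of 48 lower and 7 higher, or 30 and 7 adjusted over the list alone (adjusted p = 8.19e-09; adjusted p = 0.432 with an estimated correlation). Tenascin C, Tnc, fell from 45.6 ± 14.3 to 4.17 ± 1.05 CPM, and the collagen-crosslinking enzyme Loxl2 fell from 50.9 ± 4.37 to 22.5 ± 0.333 CPM.

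In all, 3039 genes were higher and 3218 lower at 22 weeks than at 4 weeks, 41.0% of those tested, and 592 and 694 of them by 2-fold or more. The groups did not overlap for 51.2% of tested genes, against 10% by chance. The authors' table lists 3095 higher and 3054 lower genes for these ages, of which 5673 were called in the same direction here and 0 in the opposite one.

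Capillary markers rose with age, with 11 of 15 higher and 1 lower, also when adjusted over the list alone (adjusted p = 9.44e-05; adjusted p = 0.432 with an estimated correlation). Rgcc, a marker of heart capillaries, rose 1.98-fold to 317 ± 6.97 CPM, and Cd300lg, a receptor of capillary endothelium, rose 2.09-fold to 1324 ± 93.1 CPM. Arterial markers rose as well, with 12 of 20 higher and 0 lower, or 13 and 0 adjusted over the list alone (adjusted p = 0.00106; adjusted p = 0.471 with an estimated correlation), among them Cxcl12 by a log2 change of 0.86 ± 0.08 and Stmn2 by 0.95 ± 0.10. Endocardial markers had 8 of 14 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.00731; adjusted p = 0.759 with an estimated correlation), with the growth factor Bmp6 rising 3.52-fold. The mean log2 deviation of endocardial markers was -0.08 in replicate 2 of 22-week BPH/2J against 0.34 and 0.58 in the others of its group. Without 4-week BPH/2J replicate 1 the endocardial list had an adjusted p of 0.0567. General endothelial markers were not called as a list, with 8 of 25 higher and 3 lower, or 9 and 3 adjusted over the list alone (adjusted p = 0.296). Pecam1 gave 1948 ± 113 and 1870 ± 48.0 CPM (adjusted p = 0.555).

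Of 25 growth genes known to decline after birth, 14 fell and 2 rose, as also adjusted over the list alone (adjusted p = 0.00016; adjusted p = 0.288 with an estimated correlation). The imprinted gene Mest fell from 468 ± 31.9 to 78.4 ± 31.3 CPM, while Cdkn1c, an imprinted inhibitor of the cell cycle, rose from 113 ± 16.5 to 273 ± 46.0 CPM. Sterol synthesis genes and their regulators fell, with 15 of 26 lower and 4 higher, also adjusted over the list alone (adjusted p = 0.00106; adjusted p = 0.432 with an estimated correlation). The squalene epoxidase Sqle fell by 1.11 ± 0.12 on the log2 scale, and the desaturase Scd1 rose 2.85-fold. Chaperone and unfolded protein genes had 18 of 30 lower and 2 higher, or 19 and 2 adjusted over the list alone (adjusted p = 0.00534; adjusted p = 0.759 with an estimated correlation), with the chaperone Hspa5 falling from 1114 ± 183 to 526 ± 36.4 CPM. Replicate 1 of 4-week BPH/2J, the library apart on the third component, had a mean log2 deviation of -0.17 over that list against 0.36 and 0.25 in its group and -0.38 to -0.29 at 22 weeks. The list was also called without it. The senescence list, which holds cell cycle inhibitors and secreted factors among other genes, had 12 of 24 lower and 3 higher, equal to the counts adjusted over the list alone (adjusted p = 0.00534; adjusted p = 0.432 with an estimated correlation). Its members need not all change in the same direction in senescence, so these counts give no direction for senescence itself. Lmnb1, which encodes a lamin of the nuclear envelope, fell from 85.5 ± 14.9 to 18.7 ± 3.74 CPM, and Igfbp3, a secreted binder of growth factors, rose 1.81-fold.

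The apelin precursor Apln fell from 277 ± 18.4 to 82.5 ± 22.3 CPM (adjusted p = 3.51e-05), Ace rose 1.68-fold to 271 ± 13.6 CPM (adjusted p = 0.000531), and Edn1 rose from 33.9 ± 6.07 to 58.0 ± 5.38 CPM (adjusted p = 0.0105). The stretch-gated channel Piezo2 fell by 1.72 ± 0.19 on the log2 scale, and the junction protein Jam2 rose 2.11-fold to 1073 ± 63.0 CPM. Nos3 fell from 338 ± 34.7 to 280 ± 10.9 CPM with an adjusted p of 0.0175, which became 0.0601 and 0.0913 without replicates 2 and 3 of 4-week BPH/2J, 0.0844 without replicate 1 of 22-week BPH/2J and 0.0755 with the mean cardiomyocyte level as a covariate. The lists of vasoactive peptides (10 of 28 higher, 7 lower; adjusted p = 0.707), nitric oxide and cGMP (7 of 24 higher, 7 lower; adjusted p = 0.74) and renin-angiotensin genes (7 of 15 higher, 3 lower; adjusted p = 0.092) were not called, and their counts were equal when adjusted over the list alone. The nitric oxide list had a median log2 change of 0.04 and a mean of -0.01. Prostanoid and eicosanoid genes rose as a list, with 12 of 22 higher and 3 lower, as also adjusted over the list alone (adjusted p = 0.00288; adjusted p = 0.471 with an estimated correlation). Ephx1, an epoxide hydrolase, rose from 112 ± 21.5 to 318 ± 23.4 CPM. Over the prostanoid list, replicate 2 of 22-week BPH/2J had a mean log2 deviation of -0.03 against 0.19 and 0.26 in its group. The 4-week libraries lay at -0.37 to -0.18.

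Clock genes rose as a list, with 11 of 21 higher and 6 lower, or 12 and 6 adjusted over the list alone (adjusted p = 0.000657; adjusted p = 0.471 with an estimated correlation). The nuclear receptors Rora and Nr1d2 rose by 1.08 ± 0.07 and 0.76 ± 0.07 on the log2 scale, and the core activators Arntl and Clock fell by 1.67 ± 0.22 and 0.46 ± 0.09.

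Markers of blood cells moved beside these groups. Macrophage and monocyte markers fell, with 16 of 23 lower and 2 higher, or 18 and 4 adjusted over the list alone (adjusted p = 0.000213; adjusted p = 0.759 with an estimated correlation), and the growth factor receptor Csf1r fell from 106 ± 29.6 to 38.8 ± 1.88 CPM. Lymphocyte markers rose, with 8 of 17 higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 0.00854; adjusted p = 0.759 with an estimated correlation), the T cell receptor gene Cd3d reaching 3.01 ± 0.213 against 1.51 ± 0.333 CPM. The libraries of a group spread widely in these lists, from 0.04 to 0.72 in mean log2 deviation for macrophage genes at 4 weeks and from 0.11 to 0.78 for lymphocyte genes at 22 weeks. Antigen presentation genes rose, with 14 of 25 higher and 0 lower, or 15 and 0 adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.834 with an estimated correlation), H2-T23 by 2.05-fold. Without 4-week BPH/2J replicate 1 the antigen presentation list had an adjusted p of 0.0843. The ribosomal protein list was called higher (adjusted p = 0.0101; adjusted p = 0.876 with an estimated correlation), with 12 of 64 higher and 1 lower, but 0 and 0 adjusted over the list alone. It had an adjusted p of 0.0834 without replicate 2 of 4-week BPH/2J, 0.0723 without replicate 3 of 22-week BPH/2J and 0.274 with the mean cardiomyocyte level as a covariate. Cardiomyocyte markers were not called as a list, with 4 of 24 higher and 1 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.404). Fibroblast markers had 4 of 20 higher and 7 lower, as also adjusted over the list alone (adjusted p = 0.502). The collagen gene Col3a1 fell from 220 ± 59.4 to 80.8 ± 17.6 CPM beside the matrix list, which shares it. Replicate 1 of 4-week BPH/2J stood apart in fibroblast markers, at a mean log2 deviation of 0.49 against -0.05 and -0.04 in its group.

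The largest rises with age included Fmo2, a flavin monooxygenase, from 45.7 ± 14.2 to 549 ± 78.2 CPM, and Prg4, the lubricant proteoglycan lubricin, from 5.23 ± 0.531 to 55.4 ± 3.02 CPM. Nr3c2, the mineralocorticoid receptor, rose by 2.51 ± 0.29 on the log2 scale, or 3.13 without 4-week BPH/2J replicate 1. Cyp26b1, which degrades retinoic acid, was at 4.96 ± 3.50 and 122 ± 173 CPM, a log2 change of 4.64 that was 2.17 without 22-week BPH/2J replicate 1 and 5.36 without 4-week BPH/2J replicate 2 and that was not called by limma-voom (adjusted p = 0.106) or with the cardiomyocyte covariate (adjusted p = 0.156). Besides Tnc, the largest falls included Troap, Ticrr, Ska1, Pbk and Nuf2, which act in replication or mitosis, and Adamts17, a metalloprotease, which fell from 21.1 ± 1.54 to 2.16 ± 0.801 CPM. With the replicate number as a block, 5758 genes were called between the ages.

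**Figure D4:**
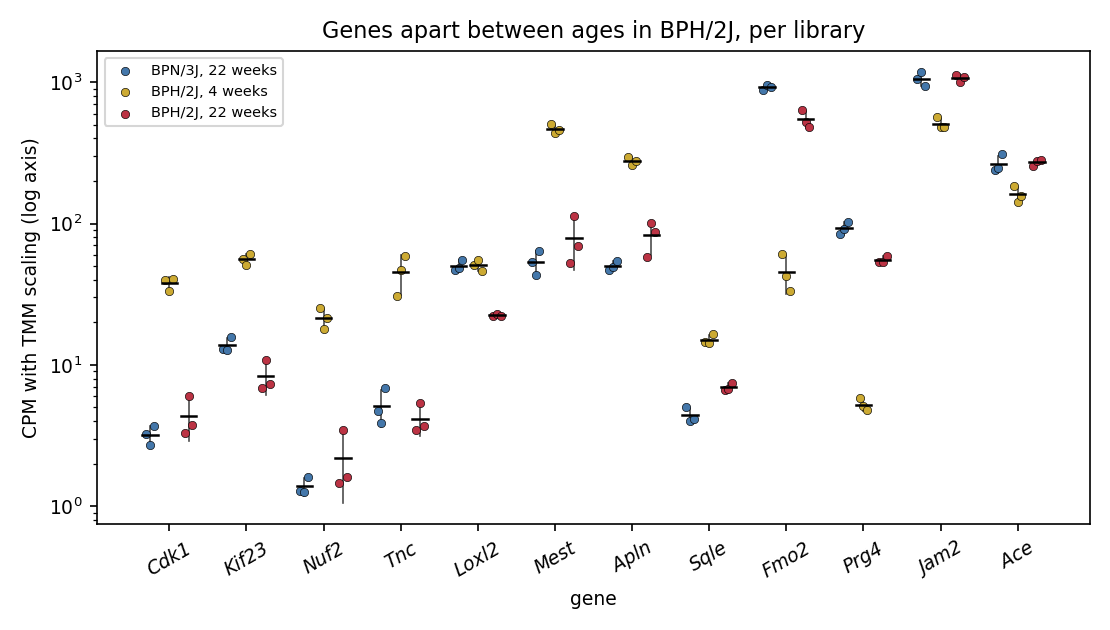
CPM with TMM scaling (log axis) of 12 genes in each of the 9 libraries, coloured by group, with the mean as a bar and the SD as a vertical line (n = 3). Cdk1, Kif23, Nuf2, Tnc, Mest, Apln and Sqle lie higher in 4-week than in 22-week BPH/2J, and Fmo2, Prg4, Jam2 and Ace lie lower.

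No 4-week BPN/3J libraries were in the series, so strain and age change together between 4-week BPH/2J and 22-week BPN/3J and cannot be separated there. Against adult BPN/3J, the young BPH/2J endothelium had 50 of 50 cell cycle genes higher, also adjusted over the list alone (adjusted p = 4.2e-40; adjusted p = 0.383 with an estimated correlation), with cyclin B1, Ccnb1, at 16.3 ± 2.13 against 0.783 ± 0.237 CPM. Matrix genes were higher, with 31 of 48 higher and 8 lower, or 32 and 8 adjusted over the list alone (adjusted p = 7.04e-07; adjusted p = 0.461 with an estimated correlation). Sparc, a matrix protein that binds collagen, was at 6220 ± 245 against 1618 ± 136 CPM, and the membrane metalloprotease Mmp15 was 5.04-fold higher. Glucocorticoid targets were lower, with 18 of 21 lower and 1 higher, as also adjusted over the list alone (adjusted p = 4.74e-10; adjusted p = 0.131 with an estimated correlation), and Klf15 differed by -4.44 ± 0.15 on the log2 scale (adjusted p = 1.25e-08). The higher member was Angptl4, a lipase inhibitor, at 50.7 ± 8.74 against 33.5 ± 10.9 CPM with overlapping libraries (adjusted p = 0.0324), a call that was lost at an adjusted p of 0.0901 without BPN/3J replicate 1, 0.107 without BPN/3J replicate 2 and 0.0924 without 4-week BPH/2J replicate 1.

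Genes called numbered 4253 higher and 3862 lower, 53.1% of those tested, with 992 and 1227 of them by 2-fold or more. Groups did not overlap for 59.2% of tested genes, against 10% by chance. The authors' table lists 4270 higher and 3981 lower, of which 7519 were called in the same direction here and 0 in the opposite one.

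Immediate early genes were lower in 4-week BPH/2J than in BPN/3J, with 22 of 30 lower and 0 higher, or 23 and 1 adjusted over the list alone (adjusted p = 4.33e-06; adjusted p = 0.499 with an estimated correlation), and Csrnp1 was 3.87-fold lower. Replicate 1 of 4-week BPH/2J lay nearer to BPN/3J (0.33 to 0.61) in the mean log2 deviation of that list, at 0.02 against -0.31 in both others, and the list was also called without it. Antigen presentation genes were lower, with 24 of 25 lower and 0 higher, or 25 and 0 adjusted over the list alone (adjusted p = 2.51e-08; adjusted p = 0.499 with an estimated correlation), and H2-T23 was at 100 ± 5.10 against 303 ± 81.7 CPM, with BPN/3J replicate 1 again highest over the list. Capillary markers were lower, with 12 of 15 lower and 1 higher, also adjusted over the list alone (adjusted p = 4.04e-06; adjusted p = 0.383 with an estimated correlation). Rgcc differed by -2.02 ± 0.08 on the log2 scale and the water channel Aqp1 was 3.49-fold lower, while the VEGF receptor Kdr was 1.55-fold higher. Sterol genes were higher, with 17 of 26 higher and 4 lower, or 18 and 4 adjusted over the list alone (adjusted p = 7.04e-05; adjusted p = 0.383 with an estimated correlation), and the sterol demethylase Cyp51 was 3.62-fold higher. Clock genes were lower, with 13 of 21 lower and 4 higher, or 14 and 4 adjusted over the list alone (adjusted p = 0.00224; adjusted p = 0.467 with an estimated correlation), Per3 at 60.8 ± 4.37 against 157 ± 11.7 CPM and Arntl at 10.2 ± 2.66 against 2.26 ± 0.471 CPM.

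In the renin-angiotensin list 9 of 15 were lower and 3 higher, as also adjusted over the list alone (adjusted p = 0.0377; adjusted p = 0.485 with an estimated correlation), with Agtrap at 27.2 ± 1.93 against 66.2 ± 3.62 CPM and the peptidase Prcp 2.23-fold higher. That list had an adjusted p of 0.056 and 0.0531 without replicates 2 and 3 of 4-week BPH/2J. Prostanoid genes had 9 of 22 lower and 3 higher, also adjusted over the list alone (adjusted p = 0.043; adjusted p = 0.499 with an estimated correlation), with the prostaglandin receptor Ptger4 at 12.0 ± 2.24 against 60.4 ± 9.77 CPM, and an adjusted p of 0.0675 without 4-week BPH/2J replicate 2 and 0.051 with the replicate number as a block. Aplnr was 10.1-fold and its ligand Apln 5.53-fold higher in young BPH/2J, and Ednrb was at 90.3 ± 5.71 against 269 ± 20.3 CPM. The channel gene Piezo2 was 10.9-fold higher, and Klf2 and Klf4 differed by -1.22 ± 0.11 and -1.08 ± 0.07 on the log2 scale. Beside these groups, 19 of 24 cardiomyocyte markers were lower and 0 higher, or 20 and 1 adjusted over the list alone (adjusted p = 0.000103; adjusted p = 0.499 with an estimated correlation), Myh6 at 44.8 ± 10.7 against 171 ± 15.2 CPM. Replicate 1 of 4-week BPH/2J stood apart here too, at a mean log2 deviation of -0.06 against -0.56 and -0.44, and in the renin-angiotensin list, at -0.02 against -0.51 and -0.43. Both lists were also called without it. With the mean cardiomyocyte level as a covariate 2639 genes were called, of which 2319 were among the 8115, and the immediate early list (adjusted p = 0.0584), the renin-angiotensin list (adjusted p = 0.64) and the prostanoid list (adjusted p = 0.579) were not. Of the 132 called genes that the naming rule took here, 33 lost their call under the covariate and 4 turned in direction. Among the lost calls were Kdr (adjusted p = 0.191), Arntl (adjusted p = 0.12), Angptl4 (adjusted p = 0.234) and Trpv4 (adjusted p = 0.62). With the replicate number as a block 7723 genes were called.

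Differences from BPN/3J were largely shared by both ages of BPH/2J. At 22 and at 4 weeks, 3834 genes were called in the same direction, 1939 higher and 1895 lower, or 66.0% of the calls at 22 weeks, and 231 were called in opposite directions. Independent lists of these sizes would share 842 higher and 704 lower genes. Among the shared genes Aplnr, Trpv4, Marveld2, Lppr1 and Gdpd3 were higher and Klf2, Klf4, Klf15, Csrnp1, Ednrb and Myh6 lower at both ages. The comparisons share the BPN/3J libraries, which are too few to divide between them, and the shared libraries can add to the overlap. In 20 simulated data sets with unchanged groups against shared libraries, edgeR gave 0 genes called in both by adjusted p. By unadjusted p under 0.05 it gave 165 on average and 186 at most, where 4714 were observed. With no gene changed, few calls by adjusted p can arise at all. The overlap that shared libraries add when many genes differ was not simulated.

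Genes of 22-week BPH/2J that stood apart from both other groups in the same direction numbered 1617, with 895 higher and 722 lower, against 602 and 587 for independent lists, and 994 genes were called in opposite directions. Loxl2 and Cdkn1a were lower in 22-week BPH/2J than in both other groups, and Cxcl12 was higher, at 3229 ± 231 CPM against 1823 ± 37.2 in BPN/3J and 1778 ± 72.6 in 4-week BPH/2J. Simulated unchanged groups gave 0 by adjusted p in edgeR, and 157 on average and 195 at most by unadjusted p under 0.05, where 2366 were observed. Here the 22-week BPH/2J libraries are shared and can add to the overlap, by an amount that these simulations do not measure. The count was 2459 without 4-week BPH/2J replicate 1, 994 without 22-week BPH/2J replicate 1 and 1029 without 22-week BPH/2J replicate 3.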

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

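The fit with the legacy setting off and the fit without annotated pseudogenes were tests chosen after seeing the data, and every gene count they gave was within 1.5 times the reported one. The same held for the counts of genes under the other scalings, filters and tools and with the replicate number as a block (5261 between the lines at 22 weeks, 5758 between the ages, 7723 between 4-week BPH/2J and BPN/3J). Leaving out each library gave 4362 to 7117, 4606 to 7383 and 6968 to 8682 genes, 7 to 12, 14 to 18 and 11 to 14 lists, and 2970 to 4187 genes shared by both ages of BPH/2J against BPN/3J. Genes shared by the comparisons of 22-week BPH/2J numbered 994 without its replicate 1, 1029 without its replicate 3 and 2459 without 4-week BPH/2J replicate 1. With an adjusted p threshold of 0.01 in place of 0.05, fewer genes can pass, and the counts were 3432 between the lines, 3871 between the ages, and 2272 and 644 for the overlaps. An estimated correlation gave 0 lists in each comparison with camera, where 2, 4 and 4 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, gave 17 lists between the lines, 19 between the ages and 28 between 4-week BPH/2J and BPN/3J. It did not call the macrophage (adjusted p = 0.0826), interferon (0.125) and ribosomal (0.151) lists between the lines, nor the antigen presentation (0.142) and ribosomal (0.274) lists between the ages, which camera called. Lists called by fry and not by camera between the lines included general endothelial (0.00122), nitric oxide and cGMP (0.0039), vasoactive peptide (0.0116), TGF-beta and BMP (0.0039) and complement (0.00493) genes. The shear-stress (0.051), adhesion (0.051), renin-angiotensin (0.0542) and ion channel (0.138) lists were called by neither. Between the ages fry called the renin-angiotensin list (0.0234) and not the vasoactive peptide (0.227) or nitric oxide (0.221) lists. The cardiomyocyte covariate, whose level itself differs between the lines, gave 3661 genes between the lines and 2639 between 4-week BPH/2J and BPN/3J. Same-number libraries had residual correlations from -0.161 to 0.077, so the numbers showed no shared batch. The group means were taken out of these residuals, so a batch that follows the groups cannot be seen in them. Such a batch cannot be told apart from strain or age.

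Some directions turned. With the covariate the cardiomyocyte list, from which it is built, turned at adjusted p = 0.882 and 0.676 in the comparisons with BPN/3J. Log2 values that turned with the covariate were Cd209f -0.043, Ifit3 -0.09, Vtn 0.022 and Itga2b 1.35 between the lines at 22 weeks, Icam1 -0.011 and Hbb-bs -0.02 between the ages, and Pdk1 0.14, Cmpk2 -0.13, Nos3 -0.10, Edn1 0.084, Kcnn3 0.54, Kcnn4 0.48, Piezo1 -0.30, Atp2a2 -0.51 and Lyz2 -0.96 between 4-week BPH/2J and BPN/3J. Nos3 between the lines, which was not called, gave 0.008 with upper-quartile scaling and 0.007 without a low-count filter. Agtr1a between the ages gave 0.008 with upper-quartile scaling, 0.211 with limma-voom and 0.016 with the replicate block. Leaving out single libraries gave ranges across 0 for Nos3 (-0.018 to 0.031), Edn1 (-0.11 to 0.34) and Ace (-0.034 to 0.153) between the lines. Between the ages it did so for Agtr1a (-0.45 to 0.31), Icam1 (-0.04 to 0.13), Trpv4 (-0.04 to 0.31), Itga2b (-0.57 to 0.26) and Hbb-bs (-0.13 to 0.33). Between 4-week BPH/2J and BPN/3J it did so for Atp2a2 (-0.023 to 0.204), Ighm (-0.20 to 0.18) and Itga2b (-0.37 to 0.47). None of the named genes called in a comparison turned when a library was left out. Beyond the construction of the threshold and of the covariate, the cause was not tested. Depth limits transcripts under about 0.104 CPM, the level that 3 counts give in the smallest library.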

Other observations

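The tests on transcripts far apart between the lines were chosen after the result was seen. Some genes of lipid handling differed between the lines. Lipoprotein lipase, Lpl, was at 2128 ± 211 CPM in 22-week BPH/2J, 1322 ± 327 in 4-week BPH/2J and 4857 ± 183 in BPN/3J (mean ± SD, 3 libraries each). The fatty acid binding protein Fabp5 was 2.55-fold higher at 22 weeks and 4.03-fold higher at 4 weeks than in BPN/3J, and the fatty acid transporter Cd36 rose 1.68-fold with age in BPH/2J. Of 40 fatty acid genes, 5 were higher and 7 lower between the lines at 22 weeks (4 and 7 adjusted over the list alone; adjusted p = 0.661). In 4-week BPH/2J against BPN/3J 8 were higher and 21 lower (8 and 22; adjusted p = 0.152), and with age in BPH/2J 15 rose and 6 fell (16 and 6; adjusted p = 0.118). Camera called the list in none of the 3 comparisons, and fry called it in the 4-week comparison (adjusted p = 0.00382) and between the ages (adjusted p = 0.0256). Xanthine dehydrogenase, Xdh, was at 967 ± 155 CPM in 22-week BPH/2J, 349 ± 51.4 in 4-week BPH/2J and 2125 ± 99.9 in BPN/3J.

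Complement and coagulation genes had 14 of 36 lower and 2 higher in 22-week BPH/2J than in BPN/3J, as also adjusted over the list alone, without a call as a list (adjusted p = 0.0899). Complement C7 was 10.9-fold lower and Cd55, which protects cells from complement, 2.51-fold higher, while C3 rose 5.01-fold with age in BPH/2J. Genes of TGF-beta and BMP signalling had 15 of 36 lower and 5 higher (16 and 5 adjusted over the list alone; adjusted p = 0.0822), with the inhibin subunit Inhbb 3.00-fold lower and Bmp4 1.62-fold higher. The Notch target Heyl was 3.05-fold lower and Esm1, a secreted product of endothelial cells, 4.34-fold higher in BPH/2J. The Y-linked gene Uty was at 65.7 ± 4.80 CPM in BPN/3J, 30.2 ± 1.16 in 4-week BPH/2J and 30.03 ± 3.17 in 22-week BPH/2J.

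Of the tested transcripts, 211 were at least 3 apart on the log2 scale between the lines at 22 weeks. A state that comes only with adult age in BPH/2J is argued against by the 4-week libraries, whose difference from BPN/3J had a median ratio of 0.982 to the 22-week difference (95% bootstrap interval 0.957 to 0.999), or 0.962 for the 145 transcripts not annotated as pseudogenes. Simulated groups with 4-week BPH/2J equal to the shared BPN/3J libraries gave ratios of -0.004 to 0.014. The age change within BPH/2J, which uses no BPN/3J library, had a median of 0.112 (0.005 to 0.255) on the log2 scale. Over the same transcripts the lines were a median of 4.94 apart. The intervals of the ratio and of the age change resample transcripts and do not measure the spread between libraries. Sequence variants that move reads between near-identical copies may account for part of the pattern, since pseudogenes were over-represented with an odds ratio of 23.1 (95% interval 16.6 to 31.9; Fisher's exact test, two-sided p = 1.29e-56). That ratio does not cover the 145 other transcripts, of which 103 are protein-coding and 42 have another annotated type or none. For these, inherited differences in expression between the lines stay open and were not tested.

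Cardiomyocyte transcripts were higher in BPN/3J than in 22-week BPH/2J. A lower share of endothelial cells with every other cell type raised alike is argued against by the mural list alone. Its median lay 0.51 above the cardiomyocyte median on the log2 scale (95% bootstrap interval 0.33 to 0.83). The fibroblast median (0.38 above, -0.01 to 0.84) and the macrophage median (-0.15, -0.52 to 0.33) were not separated from the cardiomyocyte median. These intervals resample the genes of each list and not the libraries, so they do not measure the spread between preparations. A larger share of cardiomyocyte RNA in the BPN/3J preparations, despite the bead selection, and different expression of these genes within endothelium cannot be told apart, since the 91.7% of the list (22 of 24) with a negative log2 difference would be found with either.

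Genes called between the lines at 22 weeks lay beside one another more often than in shuffled orders, with a ratio of 1.30 (95% range 1.24 to 1.37) for neighbours called in the same direction. Reads shared by overlapping or near-identical neighbours are argued against as the whole cause, because the ratio was 1.25 (1.16 to 1.36) among neighbours over 10 kb apart with different symbol stems. Blocks of inherited sequence that differ between the lines could give such a pattern, but the ratio between the ages within BPH/2J was 1.196 (1.15 to 1.26), and the ranges overlap, so blocks cannot be told apart from the neighbour effect seen without a difference in strain. Co-regulation of neighbours stays open and was not tested.

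In 1 of the 10 splits of the 6 libraries of each comparison, the real split, as many genes were called as reported. The real counts were 5810, 6257 and 8115, and the highest count of the other splits was 0 with edgeR in each comparison, or 443, 1852 and 1112 at an unadjusted p under 0.05. Every other split mixes libraries of both groups, so a real difference adds to its spread. Its count is thus not the count expected without a difference. With 3 libraries against 3, the splits are too few for a share under 0.05.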
